A study of Mus musculus with 12 samples.

How the data were processed

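RNA was measured in 12 libraries of RAW264.7 cells, 2 for each of 6 groups formed by 3 genotypes and 2 treatments. Per the labels the libraries were made from poly(A) RNA with a stranded TruSeq kit and sequenced as single reads of 75 bases on a NextSeq instrument. Per the labels the count values are reads per Ensembl gene that the authors deposited in 1 table of whole numbers without scaling, and no replicates were pooled. Per the submitters' processing notes FastQC, HISAT, StringTie, HTSeq and DESeq2 were used; versions and settings are not given in the sources used here. The deposited tables of changed genes hold log2 values, per the file headers and the group means in the same files the second group named over the first, with shrinkage. They also hold the authors' adjusted p-value for each gene, and the method of adjustment is not given in the sources used here.

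Some labels did not match the values. The processing notes name the human build GRCh38, but all gene identifiers are mouse, and 1278 of 1345 gene positions in the authors' tables (95.02%) equal those of the mouse build GRCm38, which was used for all coordinates here. The treatment protocol names HEK293T, a human cell line, while the samples are labelled as mouse macrophages. The columns of the count table were assigned to samples from the sample descriptions, and 0 columns were left unmatched. The knockout columns bear a number and no gene name, so the genotype of each comes from the title of the matched sample. Of 54232 genes 54079 had a symbol in the reference tables.

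The depth ranged from 17250815 to 24377950 counts per library, so that 3 counts correspond to 0.122 to 0.169 CPM (read counts scaled by library size). A gene with 0 counts in a group of 2 libraries is given a bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts a raw ratio with an exact binomial 95% interval, which measures counting error only. The 10 genes with the most counts held 4.76% to 7.47% of a library. The biological coefficient of variation shared by all groups was 0.289.

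Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given (12771 genes), libraries were scaled by the trimmed mean of M-values (TMM), and 1 model with a mean for each of the 6 groups was fitted with robust quasi-likelihood. Each contrast was tested by the quasi-likelihood F-test, adjusted by Benjamini-Hochberg over all tested genes, and called at an adjusted p of 0.05 without a fold threshold. All adjusted p of single genes in the text come from this edgeR test unless another tool is named. The standard errors are the absolute log2 change over the root of the F statistic. The contrasts were LPS against untreated in each genotype, each knockout against wild type without and after LPS, the difference of each knockout's LPS response from that of wild type, and the knockouts against each other.

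Gene lists were fixed before the data were examined: 30 lists with 817 symbols, of which 809 matched the table, and 27 lists with at least 5 tested members were tested. The test was camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Because genes of 1 list vary together, camera was also run with a correlation estimated for each list, and the text gives that p beside each list call that it ends. Members called over all genes were counted, and so were members called after adjustment over the list alone. Adjusted p values of lists come from limma. List medians and means, unless given by library, are of the edgeR log2 changes and not of the log2 CPM that camera tested.

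The named genes were chosen by a rule written before the data were examined. It names the targeted genes Ing4 and Socs1 and 8 inflammatory anchors, among them Tnf, Il1b, Il6, Il10, Nos2, Cxcl10 and Ifit1. For each of the 5 comparisons of LPS with untreated wild type and of knockouts with wild type it names up to 8 rises and 8 falls, those largest among called genes with a symbol other than a predicted or clone name, a mean of at least 2 CPM in the higher group and both libraries of 1 group above both of the other. For each difference of responses it names up to 5 each way. From a list that passes, or holds at least 3 called members, it names up to 4 called members with the smallest p. This gave 74 genes. Of these, 1 anchor is not reported here, and neither is 1 of the gene lists with the genes named through it; counts of genes, lists and values include them. Other genes are marked in the text as named after their values were seen.

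The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, scaling by relative log expression (RLE) or by the upper quartile, no filter, a filter at a mean of 5 CPM, a fit to the groups of a comparison only, the replicate number as a block, a test against a fold of 1.5 (glmTreat), an adjusted p of 0.01, camera with an estimated correlation, the self-contained list test fry, and leaving out each library in turn. After the data were seen, runs without the first LPS-treated Socs1 knockout library by DESeq2 and by camera with an estimated correlation, shared calls and overlaps without it, and further replicate blocks were added.

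Calls shared by the knockouts were set against the product of the list sizes over the genes tested and against 50 simulations of unchanged groups with shared controls. The edgeR test was itself tested on 10 simulated datasets of the same depth, each with 200 changed genes, for a knockout and for the LPS comparison. Changed genes were drawn from those above a minimum mean count, so recovery of genes with few counts was not measured. Each gene had 1 spread for all groups, so the wider spread of the LPS-treated Socs1 knockout pair was not simulated. The test recovered 67% to 82% of 4-fold changes for the knockout and 68% to 80% for LPS, and 7% to 21% and 12% to 23% of 2-fold changes. Between 1 and 9 unchanged genes were called per dataset, 1.12% to 8.99% of calls. A list raised 1.5-fold was called by camera in 9 of 10 datasets for each comparison, and over all datasets 0 and 1 unchanged lists were called. Genes were simulated independently, so this does not test lists whose members vary together. The raw reads were not analysed here.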

Results

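Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse macrophage line that grows in culture and makes inflammatory cytokines when it meets bacterial products. Cells of 3 genotypes were compared: wild type, a knockout of Ing4 and a knockout of Socs1. Each genotype was left untreated or given lipopolysaccharide (LPS), a cell wall component of Gram-negative bacteria that signals through Toll-like receptors (TLR), at 100 ng/ml for 3 h. This gave 6 groups with 2 libraries each. The submitters describe both knockouts as knockouts of E3 ligases, proteins that help to attach ubiquitin to others. Ing4 is also known as a reader of histone methylation in the HBO1 acetyltransferase complex, and Socs1 as a cytokine-induced inhibitor of JAK kinases. The total per library was between 17250815 and 24377950 counts over 54232 genes, and 16749 to 17583 genes had at least 1 count. Nothing in the labels says that the 2 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these samples. The first minus second library differences correlated at 0.447 to 0.601 between the untreated and LPS-treated pairs of a genotype. Between genotypes they correlated at -0.129 to 0.156. This argues against noise that is independent in each library. It does not tell separate cultures, separate clones and joint preparation of same-numbered libraries of a genotype apart.

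LPS was the main axis of the data. The first principal component held 54.4% of the variance of log2 CPM (read counts scaled by library size), and the 6 untreated libraries lay between -66.1 and -41.7 on it. Of the LPS-treated libraries, 5 lay between 62.4 and 74.4, whereas the first LPS-treated Socs1 knockout library lay at -16.2. The correlation of log2 CPM across genes between the libraries of a group was between 0.9705 and 0.9869 in 5 groups and 0.9258 in the LPS-treated Socs1 knockout. Each pair of libraries differed by far more than counting noise, with a chi-square per degree of freedom between 36.46 and 314.4, so no pair was taken for repeat deposits of 1 library. Because the 1 LPS-treated library stood apart, the number of genes called in each comparison is also given without it. The Socs1 knockout LPS group then has 1 library, and the lone sample is assumed to vary like the other groups.

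The transcripts of the targeted genes did not separate the genotypes. Ing4 (ENSMUSG00000030330, chromosome 6, 125039760 to 125049265, plus strand, GRCm38) had 2 to 10 counts per library in wild type, 6 to 29 in the Ing4 knockout and 3 to 28 in the Socs1 knockout. On the same strand Gm44597 overlaps 99.4% of the span of Ing4, and 4930557K07Rik covers all of it on the other strand. Reads that fall on both Ing4 and Gm44597 may have been assigned to neither gene, so the Ing4 counts are uncertain. Gm44597 itself had 0 to 5 counts per library. Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536, minus strand) had 4 to 12 counts in each untreated library, and in wild type it rose after LPS by a log2 of 4.73 (SE 0.579, edgeR adjusted p = 0.0049). After LPS it stood at 9.08 and 9.07 CPM in wild type, 8.79 and 8.19 in the Ing4 knockout, and 2.73 and 7.14 in the Socs1 knockout. The log2 difference of the LPS-treated Socs1 knockout from wild type was -0.89 (SE 0.473, edgeR quasi-likelihood test, adjusted p = 0.54). How the genes were disrupted is not given in the sources used here, and a gene can lose its protein and keep its transcript. The counts therefore neither check the genotype labels nor go against them.

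In wild-type cells, LPS raised cytokines, chemokines and feedback inhibitors of TLR signalling. Tnf, a central inflammatory cytokine, rose from 84.3 ± 0.69 to 7640 ± 1170 CPM (SD, n = 2 libraries per group), a log2 change of 6.50 (SE 0.953, adjusted p = 0.013). Il1b, which encodes the fever-inducing cytokine interleukin-1 beta, rose from 0.2 ± 0.0272 to 2590 ± 54.1 CPM, with a log2 change of 13.60 (SE 1.81, adjusted p = 0.0098). Lif, an interleukin-6 family cytokine, rose by a log2 of 12.60 (SE 1.35, adjusted p = 0.0038), and Il1a by 11.60 (SE 1.91, adjusted p = 0.024). The granulocyte growth factor gene Csf3 was 6810-fold higher by raw ratio (95% binomial exact interval 2330 to 33000, counting error only), and the cytokine-induced inhibitor Cish was 1120-fold higher (201 to 44300). Serpinb2, a plasminogen activator inhibitor, and the alarmin Il33 had 0 counts untreated and were at least 352-fold and at least 133-fold higher, against a floor of 3 counts over the group. Among the genes that fell, S1pr1, a receptor that guides lymphocyte and macrophage migration, had a log2 change of -3.71 (SE 0.703, adjusted p = 0.033). The transcription factor gene Klf11 fell by 3.40 on the log2 scale, the Polycomb subunit genes Cbx2 and Cbx8 by 2.92 and 2.46, and the pro-apoptotic Bmf by 2.55. Further named falls were Rnf144b (log2 -2.95), Fndc10 (-2.70) and Angptl4 (-2.63). Several familiar LPS targets did not pass. Il6 had 0 counts untreated and 15.7 ± 0.316 CPM after LPS (at least 236-fold, adjusted p = 0.19, and 0.019 without the first LPS-treated Socs1 knockout library). Nos2, the inducible nitric oxide synthase, had a log2 change of 7.13 (SE 2.02, adjusted p = 0.097, and 0.0022 without that library), and the anti-inflammatory Il10 a raw ratio of 35.1 (5.84 to 1430, adjusted p = 0.17).

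The inflammatory lists, fixed before the data were examined like all lists, designs and alternatives not named as added, moved upward in wild type. Of 33 measured NF-kB inflammatory targets, 24 rose and 0 fell (33 rose adjusted over the list alone), and 31 rose without the first LPS-treated Socs1 knockout library. Examples were the stress-protective Ier3 (log2 4.26, SE 0.308), Gadd45b (log2 3.8), the NF-kB subunit Rel (2.04) and the adhesion molecule Icam1 (2.72). The median log2 change of this list was 4.23, or 3.81 with the 3 members undetected in untreated cells at their bound. By camera its adjusted p was 1.5e-33, and adjusted p = 0.059 with an estimated correlation (0.0033 without that library). Of 18 chemokines, 12 rose and 0 fell (16 adjusted over the list alone, 16 called without that library). They included the neutrophil attractant Cxcl2 (log2 9.66), the interferon-induced Cxcl10 (9.30, SE 1.01), Ccl22 (10.20) and Ccl4 (5.46). Ccrl2, a chemokine-binding receptor on the same list, rose by 5.95. Their median was 6.64, or 6.11 with 4 undetected members at their bound (camera adjusted p = 9.5e-18, adjusted p = 0.22 with an estimated correlation and 0.0033 without that library). Of 33 negative regulators of TLR signalling, 16 rose and 0 fell (25 rose and 1 fell adjusted over the list alone; 23 called without that library). Zc3h12a, a ribonuclease that degrades cytokine mRNA, rose by a log2 of 5.18 (SE 0.282, adjusted p = 0.00019), the list member Nfkbiz by 6.06, the mRNA decay factor Zfp36 by 3.68 and Nfkbib by 2.14. Their median was 2.54 (camera adjusted p = 1.2e-18), and with all 12 libraries this was the 1 list call that held with an estimated correlation (adjusted p = 0.0036).

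Interferon response genes were higher after LPS in wild type as a list, but few single members passed. Of 53 type I interferon-stimulated genes all had a positive log2 change, 3 rose and 0 fell (26 adjusted over the list alone). With the first LPS-treated Socs1 knockout library left out 48 rose. The 3 were Oasl1 (log2 5.42), the RNA sensor Ifih1 (5.74) and the ubiquitin-like Isg15 (6.63, SE 1.36, adjusted p = 0.043). Ifit1, an antiviral translation inhibitor, had a log2 change of 8.42 (SE 2.05, adjusted p = 0.069, and 0.0014 without that library). The list median was 3.19 (camera adjusted p = 1.6e-15, adjusted p = 0.39 with an estimated correlation). Of 46 JAK-STAT components and SOCS family genes, 6 rose and 1 fell (14 and 4 adjusted over the list alone, 15 and 4 called without that library). The JAK-STAT inhibitor gene Socs3 rose by a log2 of 6.39, the kinase gene Pim1 by 4.20 and Osm by 3.70, and Il6st, the shared receptor subunit of interleukin-6 family cytokines, named after its value was seen, fell by 1.19 (camera adjusted p = 2.8e-05, adjusted p = 0.34 with an estimated correlation). None of the 23 genes of MHC class I antigen presentation passed singly (0 adjusted over the list alone, 6 called without that library), with a median of 0.73 (camera adjusted p = 5.1e-05, adjusted p = 0.34 with an estimated correlation).

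Further lists passed camera in wild type. Of 34 inflammasome and cell death effectors 3 rose (11 rose and 1 fell adjusted over the list alone; 12 and 2 called without the first LPS-treated Socs1 knockout library), among them the inflammasome sensor Nlrp3 (log2 3.79, SE 0.234) and the caspase regulator Cflar (2.54). Of 35 TLR pathway components 2 rose, the receptor Tlr2 (1.95) and the kinase-like Irak2 (1.78; 9 rose and 1 fell adjusted over the list alone, and 13 and 1 were called without that library). Of 19 immediate early genes, which respond within minutes to stimuli, 4 rose (4 adjusted over the list alone; 4 rose and 1 fell without that library): Myc (4.51), Maff (2.98), Junb (2.20) and Jund (1.66). The camera adjusted p was 0.00097, 0.0031 and 0.033 for these 3 lists, and adjusted p = 0.34, 0.34 and 0.65 with an estimated correlation. The immediate early genes lost their call (0.081) without that library. Of 50 cell cycle and proliferation genes 46 had a negative change and 1 fell, the replication licensing factor Cdc6 (log2 -1.96; 1 adjusted over the list alone), but 22 fell and 1 rose without that library. That list had a median of -0.57 (camera adjusted p = 3.2e-07, adjusted p = 0.45 with an estimated correlation). The E3 ligase partners of SOCS1 (14 genes, median 0.53, camera adjusted p = 0.0066), IL-4 and alternative activation markers (13 genes, median 0.79, 0.022), osteoclast markers (15 genes, median 0.64, 0.023), dendritic cell markers (10 genes, median 1.13, 0.02) and ribosomal proteins (39 genes, median 0.21, 0.0096) were higher by camera. The ING-containing HBO1 complex and ING family (15 genes, median -0.32, 0.038) was lower. With an estimated correlation these 6 lists had an adjusted p of 0.34, 0.34, 0.34, 0.34, 0.78 and 0.39. Their called members were Ccl22, which 2 of the lists hold, and the matrix protease gene Mmp14 (log2 4.50). Adjusted over the list alone, 0 of the E3 ligase partners rose and 1 fell, against the direction of the list, 2, 3 and 2 of the alternative activation, osteoclast and dendritic cell markers rose, 0 ribosomal proteins passed, and 1 of the ING list rose and 3 fell. With that library left out, 5 E3 ligase partners rose and 1 fell over all genes, 3 alternative activation markers rose and 1 fell, 3 osteoclast and 2 dendritic cell markers rose, 0 ribosomal proteins passed, and 1 of the ING list rose and 3 fell.

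The remaining 10 tested lists did not pass camera in wild type. Their medians were -0.19 for MHC class II antigen presentation (15 genes, adjusted p = 0.77), 0.30 for macrophage identity (34 genes, 0.38), -0.14 for p53 targets (34 genes, 0.68), 0.11 for cholesterol biosynthesis (24 genes, 0.67) and -0.25 for cholesterol efflux and LXR targets (15 genes, 0.3). They were 0.10 for glycolysis and hypoxia response (31 genes, 0.21), 0.07 for oxidative phosphorylation (33 genes, 0.38), -0.04 for the NRF2 oxidative stress response (24 genes, 0.43), 0.11 for the unfolded protein and integrated stress response (28 genes, 0.098) and -0.14 for lysosome and autophagy (35 genes, 0.44). The mean of the p53 targets was positive at 0.14, and the mean (0.30) and test of the NRF2 list pointed up against its median. Upper-quartile scaling turned the medians of cholesterol biosynthesis, glycolysis, oxidative phosphorylation and the unfolded protein response to negative values. Within these lists 7 genes rose and were named after their values were seen: the cell cycle inhibitor Cdkn1a (log2 1.67), Gadd45a (3.17), the glucose transporter Slc2a1 (1.61), the metallothionein Mt2 (2.70), the stress factors Atf3 (3.71) and Ppp1r15a (2.71) and the autophagy receptor Sqstm1 (1.64). Adjusted over the list alone, 9 p53 targets rose and 9 fell, 3 macrophage identity genes rose and 1 fell, 3 NRF2 genes rose, 2, 1 and 1 of the stress response, glycolysis and lysosome lists rose, and 0 of the other 4 lists passed. With the first LPS-treated Socs1 knockout library left out, falls were called too: 6 p53 targets rose and 9 fell, 4 macrophage identity and 4 NRF2 genes rose and 1 of each fell, 1 gene of cholesterol biosynthesis rose and 1 fell, and 1 lysosome gene rose and 2 fell. In that fit 4 glycolysis genes and 4 stress response genes rose, and 0 of the other 3 lists passed. Marker lists of other lineages were too thinly expressed to test, with 1 neutrophil and early myeloid gene (log2 0.85), 3 T, B and NK cell genes (median 0.06, or -0.06 with upper-quartile scaling) and 2 fibroblast, epithelial and erythroid genes (median -0.19) above the filter, none of them called (1 T, B and NK cell gene rose without that library).

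Across all 12771 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 369 in wild type, 241 higher and 128 lower after LPS, and 2886 genes had an unadjusted p under 0.05. Without the first LPS-treated Socs1 knockout library 1920 of 13262 genes were called, 1033 higher and 887 lower, and all 369 were among them. Upper-quartile scaling shifted the median log2 change of all genes by -0.114 and gave 220 higher among 434 called. Leaving out an untreated wild-type library left 28 or 37 calls, an LPS-treated wild-type library 82 or 57, an Ing4 knockout library 177 to 197, an untreated Socs1 knockout library 211, and the second LPS-treated Socs1 knockout library 1919. DESeq2 called 1416 genes, limma-voom 369 and a fit to these 2 groups alone 2197, and a block for each genotype and replicate number, added after the data were seen, gave 1811.

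Without LPS, the Ing4 knockout differed from wild type in a short list of genes. The labels name no clones, so here and for the Socs1 knockout an effect of the lost gene cannot be told apart from a difference between lines. The ceramide synthase gene Cers4 (chromosome 8, 4493026 to 4531680) fell from 6.64 ± 0.297 to 0.182 ± 0.134 CPM (SD, n = 2 each), a log2 change of -5.16 (SE 0.497, adjusted p = 0.0091). Tanc1, a scaffold protein gene on chromosome 2 (59612042 to 59846149), fell from 56.9 ± 2.03 to 1.96 ± 0.430 CPM (log2 -4.85, SE 0.302, adjusted p = 0.00065). The mitochondrial protein gene Chchd10 fell by 4.99 on the log2 scale, and the platelet-type chemokine Pf4 (log2 -4.04), the laminin subunit Lamb2 (-3.88) and the VEGF receptor Flt1 (-3.00) fell too. H2-M3, a non-classical MHC class I molecule that presents formylated bacterial peptides, fell from 81.1 ± 12.3 to 24.6 ± 0.242 CPM (log2 -1.72, SE 0.228, adjusted p = 0.037). Cep170b and Tmem98 fell by 2.92 and 1.81. All 4 genes that rose were named: the axon guidance gene Sema5a went from 12.5 ± 2.88 to 101 ± 15.9 CPM (log2 3.01, SE 0.251, adjusted p = 0.0043), and Agap2, the homeobox gene Hoxc4 and the phospholipid enzyme gene Cds1 rose by 5.22, 4.51 and 2.16. None of the inflammatory anchors reported here passed, with log2 differences of -0.70 for Tnf (SE 0.756), -3.73 for Nos2 (SE 2.62), -0.40 for Cxcl10 (SE 0.780) and -0.76 for Ifit1 (SE 1.63).

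**Figure D1:**
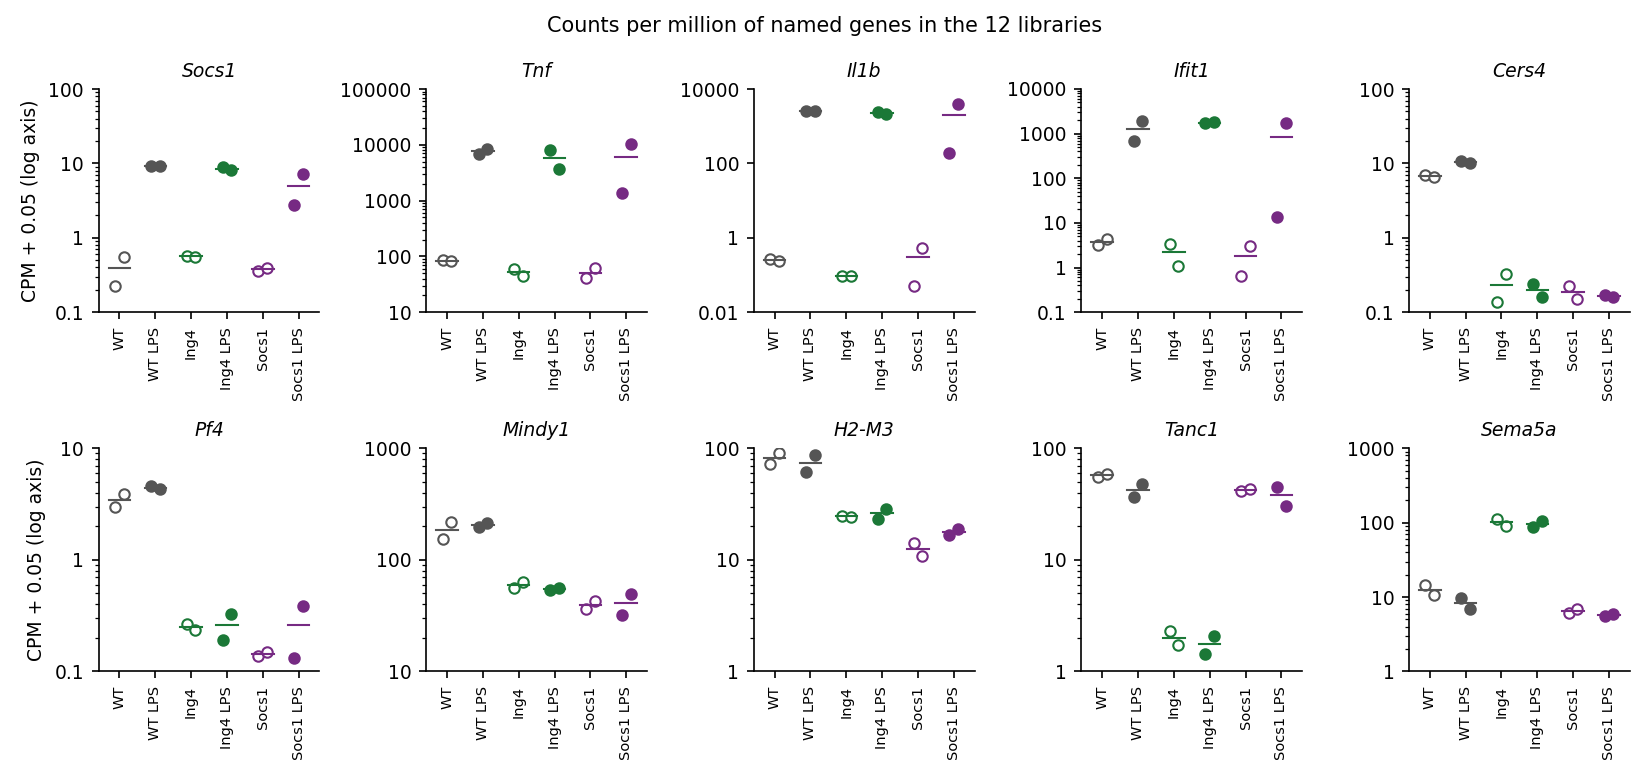
CPM plus 0.05, on a log axis, of 10 genes in the 12 libraries, with open circles for untreated and filled circles for LPS-treated libraries and bars for the mean of 2. Cers4 stands at 6.43 to 10.7 CPM in the 4 wild-type libraries and at or below 0.276 CPM in the 8 knockout libraries, and Tanc1 and Sema5a stand apart in the Ing4 knockout.

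As lists, 12 of 27 passed camera in the untreated Ing4 knockout, 10 of them lower, but their members passed singly only for H2-M3 and Flt1, and for 1 more, lower in oxidative phosphorylation, without the first LPS-treated Socs1 knockout library. Lower lists were ribosomal proteins (39 genes, median log2 -0.26, adjusted p = 7.2e-06), the unfolded protein and integrated stress response (28 genes, -0.43, 9.1e-06), MHC class I antigen presentation (23 genes, -0.45, 1.5e-05), glycolysis and hypoxia response (31 genes, -0.40, 3.4e-05) and oxidative phosphorylation (33 genes, -0.12, 0.0043). Also lower were dendritic cell markers (10 genes, -0.56, 0.0048), type I interferon-stimulated genes (53 genes, -0.63, 0.0055), MHC class II antigen presentation (15 genes, -0.64, 0.033) and chemokines (18 genes, -0.89, 0.034). The IL-4 and alternative activation list tested as lower (0.043) with a mean of -0.62 but a median of 0.13. TLR pathway components (median 0.13, adjusted p = 0.028) and cholesterol biosynthesis (0.22, 0.022) were higher. For these 12 lists the adjusted p ranged from 0.61 to 0.82 with an estimated correlation, so none of the calls held. Adjusted over the list alone, Zbtb46, Cd24a and Irf4 were lower among dendritic cell markers, Flt1, Mgl2 and Irf4 among IL-4 markers, H2-M3 for MHC class I and Sdha for oxidative phosphorylation, Cxcl16 was higher among chemokines, and the other lists named here had 0. These genes were named after their values were seen, apart from H2-M3 and Flt1. Leaving out the second untreated wild-type library left 5 lists and the first untreated Ing4 knockout library 7.

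Of 12771 genes tested, edgeR called 18 for the untreated Ing4 knockout, 4 higher and 14 lower, with 670 at an unadjusted p under 0.05. The count was 46 without the first LPS-treated Socs1 knockout library, 13 higher and 33 lower, and all 18 were among them. Leaving out an untreated wild-type library left 2 or 1, an untreated Ing4 knockout library 2 or 3, an LPS-treated wild-type or Ing4 knockout library 8, an untreated Socs1 knockout library 9, and the second LPS-treated Socs1 knockout library 47. DESeq2 called 132 genes, limma-voom 33 and a fit to these 2 groups alone 177.

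After LPS, the Ing4 knockout differed from LPS-treated wild type in many of the genes just named. Cers4 stood at 0.150 ± 0.0561 CPM against 10.4 ± 0.498 in wild type (SD, n = 2 each; log2 -6.04, SE 0.520, adjusted p = 0.0038), and Tanc1 at 1.71 ± 0.474 against 41.9 ± 7.99 (log2 -4.62, SE 0.302, adjusted p = 0.001). Chchd10, Lamb2, Pf4, Cep170b and Tmem98 were lower by log2 changes of -4.95, -4.58, -4.37, -2.99 and -2.08, and Coro2a, an actin-binding coronin gene, by -3.86. Sema5a rose by a log2 of 3.54 (SE 0.259, adjusted p = 0.0014) and Agap2 by 5.73. The last of the 3 higher genes, A230056P14Rik (log2 4.54, adjusted p = 0.0499), was named after its value was seen. Tnf stood at 5830 ± 3010 CPM against 7640 ± 1170 (log2 -0.39, SE 0.750) and Il1b at 2280 ± 148 against 2590 ± 54.1 (log2 -0.18, SE 1.03), and neither passed. Il10 had 3.8 and 24.2 CPM in the Ing4 knockout libraries against 1.40 and 0.203 in wild type (log2 4.13, SE 1.21, adjusted p = 0.45). The log2 differences of Il6 (0.60), Nos2 (-1.17), Cxcl10 (-0.20) and Ifit1 (0.47) did not pass either.

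Among lists, 7 passed camera in this comparison. Cholesterol biosynthesis was higher (24 genes, median log2 0.32, adjusted p = 0.00037), and the unfolded protein and integrated stress response (28 genes, -0.51, 1.2e-05), ribosomal proteins (39 genes, -0.23, 3.1e-05), MHC class I antigen presentation (23 genes, -0.36, 6e-04), glycolysis and hypoxia response (31 genes, -0.45, 6e-04), oxidative phosphorylation (33 genes, -0.17, 6e-04) and MHC class II antigen presentation (15 genes, -0.94, 0.046) were lower. The adjusted p of these 7 was 0.78 to 0.8 with an estimated correlation, and no member was called over all genes (1 lower in MHC class I and 1 in oxidative phosphorylation without the first LPS-treated Socs1 knockout library). Adjusted over the list alone H2-M3 and Sdha were lower and the other 5 lists had 0. NF-kB targets (median 0.14, adjusted p = 0.61) and type I interferon-stimulated genes (median -0.12, adjusted p = 0.93) did not pass, with Ier3 lower (log2 -1.61, named after its value was seen) and 0 interferon-stimulated genes called adjusted over the list alone. Leaving out the second LPS-treated wild-type library left 1 list and the first LPS-treated Ing4 knockout library 4. By edgeR 13 genes were called, 3 higher and 10 lower, with 906 at an unadjusted p under 0.05. It called 40 without the first LPS-treated Socs1 knockout library, 10 higher and 30 lower, with all 13 among them. Leaving out an LPS-treated wild-type library left 6 or 5, an LPS-treated Ing4 knockout library 4, an untreated library of either knockout 7, and the second LPS-treated Socs1 knockout library 38. DESeq2 called 139 genes, limma-voom 32 and a fit to these 2 groups alone 72.

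Whether the LPS response of the Ing4 knockout differed in size from that of wild type was tested as a difference of differences. No gene passed by edgeR (0 of 12771, with 53 at an unadjusted p under 0.05; 0 by DESeq2 and 0 by limma-voom), and without the first LPS-treated Socs1 knockout library the count was again 0, with 113 at an unadjusted p under 0.05. The difference in log2 response was 0.31 for Tnf (SE 1.06), 0.20 for Cxcl10 (SE 1.04), 1.23 for Ifit1 (SE 2.20) and -0.70 for Socs1 (SE 0.750), all with an adjusted p of 1. Of the lists, NF-kB inflammatory targets (26 of 33 positive, median 0.53, camera adjusted p = 0.0047), negative regulators of TLR signalling (25 of 33 positive, median 0.30, 0.0055) and type I interferon-stimulated genes (48 of 53 positive, median 0.51, 0.0047) had a larger rise in the Ing4 knockout, with 0 members called and 0 adjusted over the list alone. None held with an estimated correlation, where the adjusted p was 0.97, 0.47 and 0.97. Against wild type the medians of these lists were -0.34, -0.12 and -0.63 untreated and 0.14, 0.17 and -0.12 after LPS. The larger rise thus went with lower untreated medians, and after LPS the interferon-stimulated median was not above wild type. The number of lists was 0 without the second untreated wild-type library, 1 and 7 without the first and second LPS-treated wild-type libraries, 7 without the second untreated Ing4 knockout library, and 5 and 8 without the first and second LPS-treated Ing4 knockout libraries.

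Without LPS, the Socs1 knockout had 6 genes lower than wild type and 0 higher, and all 6 are named. Cers4 fell to 0.136 ± 0.0522 CPM against 6.64 ± 0.297 (SD, n = 2 each; log2 -5.53, SE 0.514, adjusted p = 0.011), and H2-M3 to 12.5 ± 2.32 against 81.1 ± 12.3 (log2 -2.70, SE 0.237, adjusted p = 0.011). Mindy1, a deubiquitinase gene on chromosome 3 (95281345 to 95296166), fell from 187 ± 46.6 to 39.3 ± 4.74 CPM (log2 -2.25, SE 0.241, adjusted p = 0.024). The pyrimidine-degrading enzyme gene Dpys had 2 counts in the knockout and was 43.8-fold lower (95% binomial exact interval 11.8 to 367, counting error only), and Nptxr, a pentraxin receptor gene, and Pf4 fell by 5.25 and 5.11 on the log2 scale. None of the cytokine and interferon anchors reported here passed, with log2 differences of -0.71 for Tnf (SE 0.757), 0.51 for Cxcl10 (SE 0.760) and -1.06 for Ifit1 (SE 1.67).

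As lists, 10 passed camera in the untreated Socs1 knockout, 9 of them lower. These were MHC class I antigen presentation (23 genes, median log2 -0.60, adjusted p = 1.4e-07), macrophage identity (34 genes, -0.31, 0.00017), type I interferon-stimulated genes (53 genes, -0.69, 0.0014), glycolysis and hypoxia response (31 genes, -0.40, 0.0014), the unfolded protein and integrated stress response (28 genes, -0.34, 0.0014), IL-4 markers (13 genes, -0.94, 0.0035), ribosomal proteins (39 genes, -0.16, 0.0068), chemokines (18 genes, -1.21, 0.031) and immediate early genes (19 genes, -0.48, 0.031). Cell cycle and proliferation was higher (50 genes, 0.14, 0.0066). Their adjusted p was 0.53 to 0.82 with an estimated correlation, so none held. H2-M3 was the 1 called member (without the first LPS-treated Socs1 knockout library 1 was lower in each of MHC class I, macrophage identity, IL-4 markers and chemokines), and adjusted over the list alone Axl and Lyz1 (macrophage identity), Flt1 and Mgl2 (IL-4 markers) were lower too, named after their values were seen, with 0 in the other lists. Leaving out the second untreated wild-type library left 6 lists. By edgeR 6 genes were called and 658 had an unadjusted p under 0.05. There were 24 calls without the first LPS-treated Socs1 knockout library, 1 higher and 23 lower, and these held all 6. Leaving out an untreated wild-type library left 0, an LPS-treated wild-type library 1, an Ing4 knockout library 3, an untreated Socs1 knockout library 0 or 1, and the second LPS-treated Socs1 knockout library 24. DESeq2 called 90 genes and limma-voom 8.

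After LPS, 8 genes were lower in the Socs1 knockout than in LPS-treated wild type and 0 higher. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 786 ± 1.21 CPM against 3970 ± 307 (SD, n = 2 each; log2 -2.34, SE 0.270, adjusted p = 0.023). Cers4 was lower by a log2 change of -6.39 (SE 0.533, adjusted p = 0.0085), Mindy1 by -2.33, H2-M3 by -2.07, Pf4 by -4.43, the Notch ligand-like Dner by -4.19, the homeobox gene Hhex by -1.83 and Cuedc1 by -1.63. All 8 lost their call without the first library of this group, where the adjusted p was 0.1 to 0.14 and 0 of 13262 genes were called by edgeR (1442 at an unadjusted p under 0.05, 163 called by DESeq2). The log2 changes then were -6.45 for Cers4, -2.33 for Odc1, -2.06 for Mindy1 and -3.67 for Pf4, estimated from 1 library. Tnf was 1380 and 10500 CPM in the 2 knockout libraries against 6810 and 8470 in wild type (log2 -0.36, SE 0.750), and Il6 0.163 and 73.2 against 15.5 and 16.0 (log2 1.22, SE 1.91). The other anchors reported here did not pass either, with log2 differences of -0.35 for Il1b, 0.94 for Il10, -1.49 for Nos2, -0.57 for Cxcl10 and -0.59 for Ifit1. Apart from Il10 these values average knockout libraries that lay far apart. Il1b stood at 196 and 3860 CPM there against 2550 and 2630 in wild type, and Nos2 at 0.774 and 185 against 110 and 412. Cxcl10 stood at 478 and 2100 against 1220 and 2600, and Ifit1 at 13.6 and 1690 against 669 and 1880.

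Of the lists, 13 passed camera after LPS and 3 without the first library of this group. Those 3 were all lower: MHC class I antigen presentation (23 genes, median log2 -0.65, adjusted p = 9.5e-09, and 0.0018 without that library), IL-4 and alternative activation markers (13 genes, -0.89, 0.0029, and 0.038) and glycolysis and hypoxia response (31 genes, -0.43, 0.002, and 0.019). The other lower lists reported here were type I interferon-stimulated genes (53 genes, -0.66, 6.3e-10, and 0.071 without that library, where the median was 0.20), chemokines (18 genes, -0.86, 0.00022, and 0.98), macrophage identity (34 genes, -0.27, 0.0012, and 0.088), NF-kB inflammatory targets (33 genes, -0.36, 0.0037, and 0.24) and ribosomal proteins (39 genes, -0.16, 0.019, and 0.068). Higher were cell cycle and proliferation (50 genes, 0.52, 6.2e-07, and 0.95 without that library), cholesterol biosynthesis (24 genes, 0.29, 0.00034, and 0.11), the ING-containing HBO1 complex and ING family (15 genes, 0.39, 0.0047, and 0.16) and immediate early genes (19 genes, 1.15, 0.033, and 0.16). The medians of type I interferon-stimulated genes, chemokines, NF-kB targets, immediate early genes and cell cycle genes turned sign without that library. With an estimated correlation the adjusted p of these lists was 0.61 to 0.78. Apart from H2-M3 no member was called over all genes. Adjusted over the list alone the members were H2-M3, Flt1, Mgl2, Slc2a1, Lyz1, Maf, Ier3 and Ptges lower and Rel, Cenpe and Hmmr higher, named in part after their values were seen, with 0 in the other 6 lists given.

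By edgeR the 8 genes were called among 12771, with 1356 at an unadjusted p under 0.05. Leaving out the first LPS-treated wild-type library left 4 and the second 0, an Ing4 knockout library 1, the first library of the group itself 0 and the second 1196. DESeq2 called 230 genes, limma-voom 24 and a fit to these 2 groups alone 0.

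The difference between the LPS responses of the Socs1 knockout and wild type gave 0 genes by edgeR (102 of 12771 at an unadjusted p under 0.05; 0 by DESeq2 and 0 by limma-voom). Without the first LPS-treated Socs1 knockout library the count was 0 with 250 at an unadjusted p under 0.05 (5 by DESeq2), and without the second library of that group it was 61. The difference in log2 response was 0.35 for Tnf (SE 1.06), -0.58 for Il1b (SE 2.29), -1.08 for Cxcl10 (SE 1.03) and -0.84 for Socs1 (SE 0.788). The LPS-treated Socs1 knockout libraries lay apart for these genes, so each value averages unlike libraries. Of the lists, 7 passed camera, of which 6 are reported here: immediate early genes (19 genes, median 2.17, adjusted p = 1.2e-06), cholesterol biosynthesis (24 genes, 0.28, 3e-04), cell cycle and proliferation (50 genes, 0.38, 0.00033) and p53 targets (34 genes, 0.28, 0.02) were higher. Type I interferon-stimulated genes (53 genes, 1e-05) and chemokines (18 genes, -0.19, 0.02) were lower. For the type I interferon-stimulated genes the median (0.03) and mean (0.11) were positive while the test pointed down, and the median was -0.02 with upper-quartile scaling. The median and mean come from edgeR's fitted group means, whereas camera averages log2 CPM over libraries. On that scale the list rose by a median of -0.34 and 4.62 in the Socs1 knockout libraries and 2.61 and 3.50 in wild type. No member passed over all genes and 0 passed adjusted over the list alone, and all 6 had adjusted p = 0.89 with an estimated correlation. Without the first library of that group 1 library remained in it, so only effect sizes are given. The medians were then 0.89 for type I interferon-stimulated genes, 0.49 for chemokines and -0.23 for cell cycle genes. Each direction was opposite to that of the test with all libraries. Immediate early genes rose by a median log2 of 3.49 and 1.15 in the first and second Socs1 knockout libraries. They rose by 0.11 and 0.75 in wild type and by 1.15 and 0.63 in the Ing4 knockout. Cholesterol biosynthesis stood at 0.527 and 0.367 in the Socs1 knockout against 0.405 and -0.168 in wild type. For p53 targets the values were -0.0525 and 0.0319 against -0.194 and -0.127. The number of lists was 11 and 2 without the first and second LPS-treated wild-type libraries, 4 without the first untreated Socs1 knockout library, and 6 and 11 without the first and second LPS-treated Socs1 knockout libraries.

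**Figure D2:**
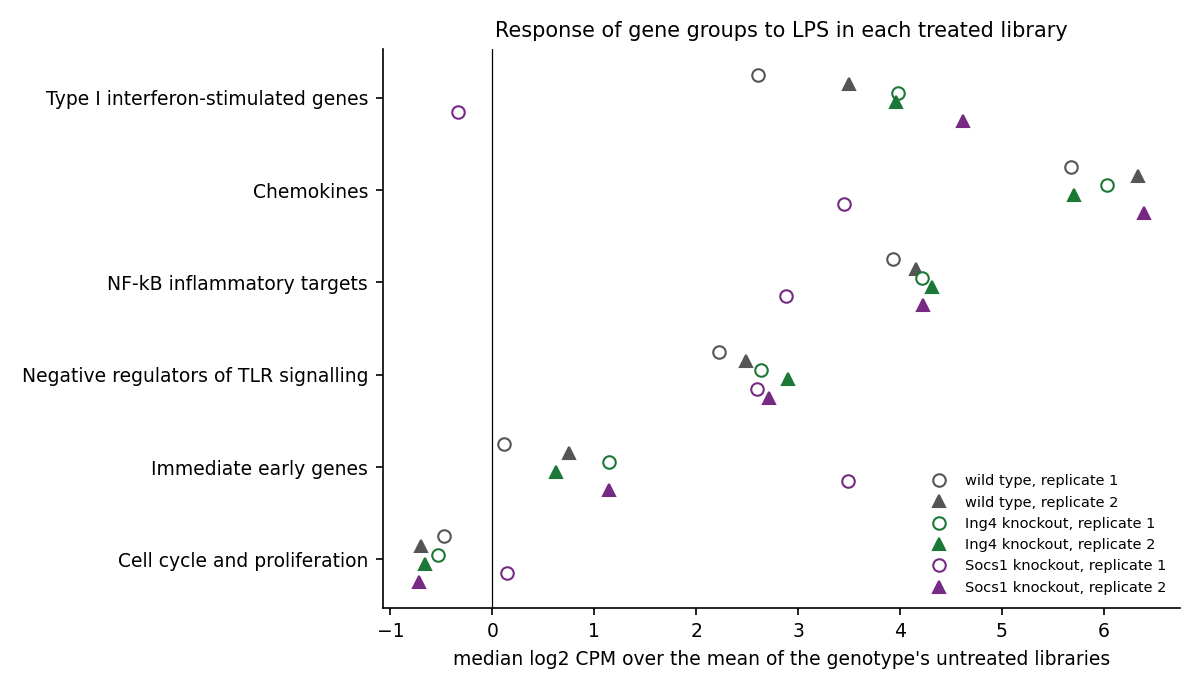
Median log2 CPM of 6 groups of genes in each LPS-treated library minus the mean of the untreated libraries of its own genotype, with open circles for replicate 1 and filled triangles for replicate 2. For type I interferon-stimulated genes the first Socs1 knockout library lies at -0.34 and the other 5 between 2.61 and 4.62, while for immediate early genes it lies at 3.49 and the other 5 between 0.11 and 1.15.

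Each knockout's own LPS response shared its direction with wild type. All 369 genes called in wild type had a log2 change of the same sign in both knockouts, 354 of them were called the same way in the Ing4 knockout and 186 in the Socs1 knockout, and 0 were called the opposite way. Independent lists of these sizes would share 11.4 higher and 4.21 lower calls with the Ing4 knockout, where 236 and 118 were shared, and 3.79 and 0.521 with the Socs1 knockout, where 151 and 35 were shared. The spread was estimated over all 12 libraries, so genes on which the LPS-treated Socs1 knockout libraries disagreed were less likely to be among the 369. The agreement with the Socs1 knockout is therefore partly built in. Of 33 NF-kB inflammatory targets 28 rose in the Ing4 knockout and 23 in the Socs1 knockout (31 and 30 without the first LPS-treated Socs1 knockout library), and of 33 negative regulators of TLR signalling 21 and 18 rose (25 and 25). Of 18 chemokines 12 and 8 rose (16 and 15), and of 53 type I interferon-stimulated genes 7 and 3 (52 and 53). By library, the median type I interferon-stimulated gene was higher than in untreated cells by a log2 of 2.61 and 3.50 in wild type, 3.98 and 3.96 in the Ing4 knockout, and -0.34 and 4.62 in the Socs1 knockout. All 53 of these genes had their lowest LPS-treated value in the first Socs1 knockout library, as did 25 of 33 NF-kB targets and 17 of 18 chemokines, and 15 of 19 immediate early genes had their highest value there. Negative regulators of TLR signalling stood at 2.60 and 2.72 in the Socs1 knockout libraries and at 2.22 and 2.49 in wild type.

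In numbers, edgeR called 1024 genes for LPS in the Ing4 knockout, 604 higher and 420 lower (2708 without the first LPS-treated Socs1 knockout library, 1481 and 1227), and 253 in the Socs1 knockout, 201 higher and 52 lower (2090, 1197 and 893). Upper-quartile scaling gave 501 higher of 1137 and 165 higher of 256, with median shifts of all genes of -0.128 and -0.136. For the Ing4 knockout, leaving out an untreated wild-type library left 399, an LPS-treated one 508 or 516, its own untreated libraries 91 or 77, its own LPS-treated libraries 218 or 194, an untreated Socs1 knockout library 592 or 589, and the second LPS-treated Socs1 knockout library 2703. For the Socs1 knockout, leaving out a wild-type library left 153 to 157 and its own untreated libraries 64 or 49. A fit to the 2 groups of the comparison alone called 1820 in the Ing4 knockout and 0 in the Socs1 knockout. DESeq2 called 2159 and 830, and a block for each genotype and replicate number, added after the data were seen, gave 3471 and 769.

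**Figure D3:**
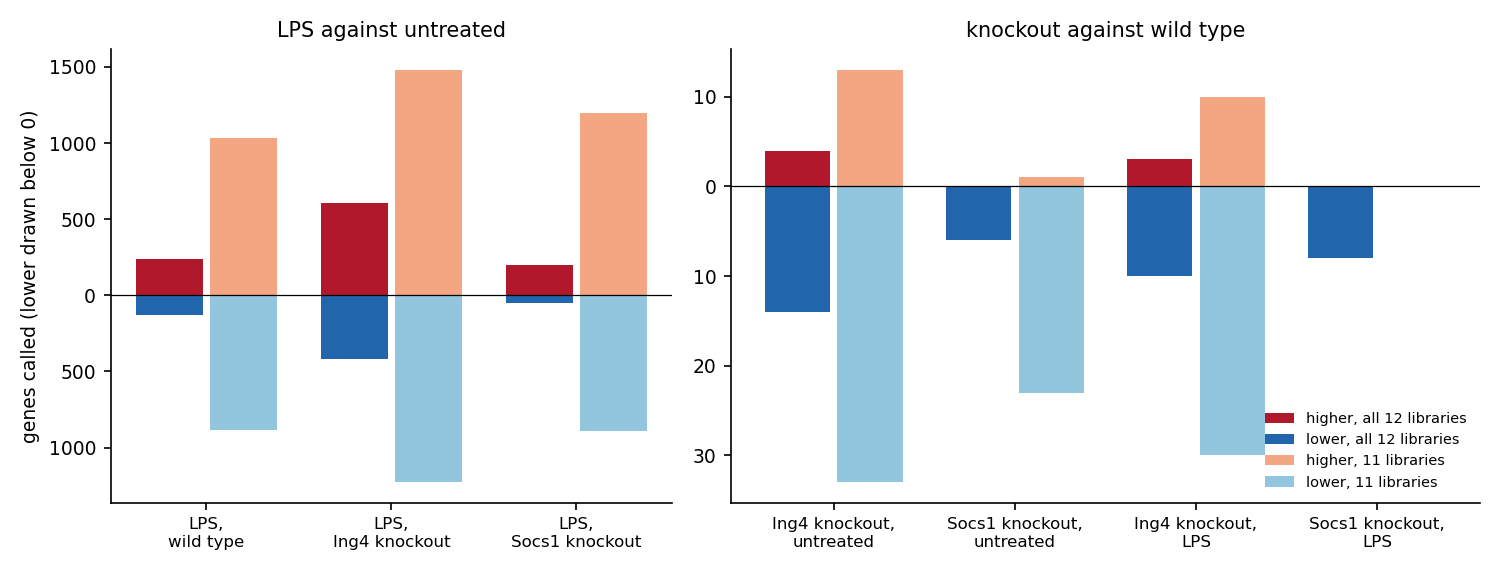
Number of genes called by edgeR at an adjusted p of 0.05 in each comparison, as bars from 0 for higher and lower genes, with all 12 libraries and with the 11 that remain without the first LPS-treated Socs1 knockout library. The LPS comparisons rise from 369, 1024 and 253 to 1920, 2708 and 2090, and the LPS-treated Socs1 knockout against wild type goes from 8 to 0.

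Compared directly, the 2 knockouts differed in the genes that set the Ing4 knockout apart. Without LPS, 6 genes were called: Tanc1 was higher in the Socs1 than in the Ing4 knockout (log2 4.42, SE 0.297, adjusted p = 0.00064), as were Chchd10 (4.16), Lamb2 (4.02), Tmem98 (2.46) and the orphan receptor gene Gpr179 (2.44), and Sema5a was lower (-3.97, SE 0.264). Gpr179 was named after its value was seen. After LPS the same 6 genes were called, with log2 differences of 4.47 for Tanc1 and -4.08 for Sema5a, among 11 in all, 6 higher and 5 lower. The 5 others, named after their values were seen, were Lrguk (log2 2.42, higher) and Gm47507 (-4.14), Gm9732 (-3.46), Mkx and Shisa3, lower. Mkx and Shisa3 had 1 and 0 counts in the LPS-treated Socs1 knockout, so no fold is given. Without the first LPS-treated Socs1 knockout library 22 genes were called without LPS and 9 after LPS, and the 6 genes were called in both. The counts at an unadjusted p under 0.05 were 391 and 923. DESeq2 called 83 and 101, and fits to the 2 groups alone called 4 and 0. Without LPS, leaving out an Ing4 knockout library of the pair left 3 or 2, the second untreated Socs1 knockout library 11 and either LPS-treated Socs1 knockout library 22. After LPS, leaving out a wild-type library left 5 or 6, an untreated Ing4 knockout library 5, an LPS-treated one 4 or 2, and the second LPS-treated Socs1 knockout library 1031.

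The calls of the knockouts against wild type overlapped. Without LPS, Cers4, H2-M3, Mindy1 and Pf4 were lower in both knockouts, 4 of 14 and 6 lower calls, where independent lists would share 0.0066. After LPS, Cers4, Mindy1 and Pf4 were lower in both, 3 of 10 and 8, where independent lists would share 0.0063. Both comparisons use the same wild-type libraries, so 50 simulations of unchanged groups against shared controls were run, which gave 0.02 shared calls on average and at most 1. The log2 differences of the knockouts correlated across genes, which are not independent replicates, at r = 0.547 without LPS and 0.473 after LPS, against 0.5 and 0.505 in the simulations. Their covariance was 0.341 and 0.317 against simulated values of 0.163 and 0.168, a difference of 0.178 and 0.148. After LPS the correlation was below the simulated one, so the larger covariance there went with larger log2 differences, not with closer agreement. The 2 wild-type libraries per condition were not split between the knockouts, which would leave 1 control for each. Part of the excess in shared calls and covariance may therefore come from the shared controls. Without the first LPS-treated Socs1 knockout library 14 calls were shared without LPS, 13 lower and Hoxc4 higher, and 0 after LPS.

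The submitters deposited tables of changed genes for 5 of these comparisons. Each gene in them was protein coding with an absolute log2 change of at least 1. The authors' deposited table for LPS in wild type holds 867 genes, 518 higher and 349 lower, and all 867 had the same sign here, with 275 called (822 without the first LPS-treated Socs1 knockout library). For the Ing4 knockout the authors' deposited tables hold 104 genes without LPS and 117 after LPS, all with the same sign here, and 17 and 12 were called here (36 and 33). For the Socs1 knockout the authors' deposited tables hold 74 and 183 genes, all with the same sign here, and 6 and 8 were called here (16 and 0). Il10 after LPS in the Ing4 knockout is among the genes not called here, with a log2 change of 2.68 and an adjusted p of 0.00072 in the authors' deposited table. Cers4 has log2 changes of -4.19 and -4.35 in the authors' deposited tables for the untreated Ing4 and Socs1 knockouts.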

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

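The results here were flagged by 1 rule: a list whose LPS response differed between a knockout and wild type by a test of that difference (camera on the difference of responses). In the Ing4 knockout the response was larger for NF-kB inflammatory targets (adjusted p = 0.0047, median difference 0.53), negative regulators of TLR signalling (0.0055, 0.30) and type I interferon-stimulated genes (0.0047, 0.51). With an estimated correlation the adjusted p was 0.97, 0.47 and 0.97. Against wild type the medians of these lists were -0.34, -0.12 and -0.63 untreated and 0.14, 0.17 and -0.12 after LPS, so the larger response went with lower untreated medians. In the Socs1 knockout the response was larger for immediate early genes (adjusted p = 1.2e-06), cholesterol biosynthesis (3e-04), cell cycle and proliferation (0.00033) and p53 targets (0.02), and by the test smaller for type I interferon-stimulated genes (1e-05, with a positive median of 0.03 and mean of 0.11) and chemokines (0.02). With the first LPS-treated Socs1 knockout library left out, 1 library remained in that group. The direction then turned for interferon-stimulated genes, chemokines and cell cycle genes. Immediate early genes had risen by a median log2 of 3.49 in the first and 1.15 in the second LPS-treated Socs1 knockout library. In the wild-type libraries they had risen by 0.11 and 0.75. With all libraries in, all 6 lists had adjusted p = 0.89 by camera with an estimated correlation. No single gene passed in either knockout by edgeR.

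All 5 tests below were chosen after the results they measure were seen, and 3 patterns were weighed.

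The first pattern is the weak LPS response of the first LPS-treated Socs1 knockout library. Admixture of untreated Socs1 knockout cells or RNA would leave the same share of the response in each group of genes, but the median share was 16.1% for NF-kB targets and -1.35% for type I interferon-stimulated genes, a ratio of -0.0839 (95% bootstrap interval over genes -0.183 to -0.0143), which argues against admixture as the whole cause. A response to Socs1 loss common to both libraries is argued against too, because in the second library the genes raised in wild type rose by a log2 of 0.42 (0.252 to 0.536) more than in the lower wild-type library. Their median rise was 2.56 there and 2.14 and 2.47 in the wild-type libraries. The interval is over genes and does not cover the spread between libraries. A shorter LPS exposure would leave early genes high and late genes low, and the immediate early genes of this library lay 2.34 (1.15 to 4.16) above the highest of the other 5 LPS libraries. That explanation, of which a mislabelled time point would be 1 form, fits and was not excluded, but it was found from these data. A weaker dose or another handling difference was not tested and stays open as well.

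The second pattern is the set of genes lower in both knockouts, such as Cers4, H2-M3, Mindy1 and Pf4. Both comparisons share the untreated wild-type libraries, so chance values of those could make such a set. The 13 genes called lower in both knockouts without the first LPS-treated Socs1 knockout library were all lower in the LPS-treated libraries of both. The higher of the knockouts' median log2 differences in the LPS libraries was -2.57 (95% bootstrap interval over genes -3.69 to -1.9), which argues against chance confined to the untreated controls. The first minus second library differences of untreated and LPS-treated wild-type cells correlated at 0.447, so the test is not independent of deviations that a wild-type culture carries into its LPS library, and whether the wild-type culture had drifted or the knockouts share a step of their making was not tested and stays open, and no biological explanation was tested.

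The third pattern is that same-numbered libraries of 1 genotype deviate together. In the Socs1 knockout Gpr34 had 0.52 and 208 CPM in the first and second untreated libraries and 0.326 and 73.2 CPM in the LPS-treated ones. A culture or sequencing day shared by all libraries with the same number would make these deviations correlate across genotypes, but the median correlation over 12 pairs was 0.053 (range -0.129 to 0.156), which argues against it. No biological explanation was tested, and separate clones, cultures or preparations behind the replicate numbers of a genotype stay open.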

How the results depend on the processing

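Values run in this order unless said otherwise: LPS in wild type, the Ing4 knockout without and after LPS, the Socs1 knockout without and after LPS, LPS in the Ing4 knockout, LPS in the Socs1 knockout, and the Socs1 against the Ing4 knockout without and after LPS (edgeR counts 369, 18, 13, 6, 8, 1024, 253, 6 and 11). DESeq2 called 1416, 132, 139, 90, 230, 2159, 830, 83 and 101 genes, shared 39 and 54 calls between the knockouts without and after LPS, and called 858, 102, 107, 70 and 158 genes of the authors' tables in the first 5 comparisons. Without the first LPS-treated Socs1 knockout library DESeq2 called 2294, 180, 208, 170, 163, 3036, 2585, 116 and 89, and 5 for the difference of LPS responses of the Socs1 knockout. With no filter edgeR called 2080, 516, 539, 429, 919, 2588, 1462, 359 and 766 genes, and 26 and 64 for the differences of LPS responses of the Ing4 and Socs1 knockouts. For DESeq2 and the missing filter the cause was not tested.

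Fits to the groups of a comparison alone, with fewer libraries, moved LPS in wild type to 2197, the Ing4 knockout to 177 and 72, the LPS-treated Socs1 knockout to 0, LPS in the knockouts to 1820 and 0, and the LPS-treated knockouts against each other to 0. The fold threshold of 1.5, stricter by construction, left 124, 7 and 8, 1 for the LPS-treated Socs1 knockout, 239 and 140 for LPS in the knockouts and 6 for the LPS-treated knockouts. The adjusted p of 0.01 left 67, 5, 6, 0, 1, 148 and 92, 5 for the LPS-treated knockouts, and 0 and 1 shared calls. Limma-voom gave 33 and 32 for the Ing4 knockout, 24 for the LPS-treated Socs1 knockout and 11 for the untreated knockouts. The mean of 5 CPM, with fewer genes, gave 9 and 8 for the Ing4 knockout, 2 for the untreated Socs1 knockout and 6 for the LPS-treated knockouts. Scaling by RLE or upper quartile kept the total of each comparison within 1.5 times, but with upper-quartile scaling not the number of lower genes for LPS.

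The replicate number as a block gave 18 for the LPS-treated Socs1 knockout and 14 and 19 for the knockouts against each other, and changed no other count by over 1.5 times. The first minus second library differences correlated at 0.447 to 0.601 between the untreated and LPS-treated pairs of a genotype and at -0.129 to 0.156 between genotypes. That argues against a strong batch shared by number, but a weak one cannot be excluded. A block for each genotype and replicate number, added after these correlations were seen, gave 1811 for LPS in wild type and 3471 and 769 in the knockouts, and 0 for the differences of responses. The crossed block, with the Socs1 knockout numbers swapped, gave 15 for the LPS-treated knockouts.

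Of the lists called by camera, 1 held for LPS in wild type with an estimated correlation and 0 in each other comparison, 3 and 0 without the first LPS-treated Socs1 knockout library, and fry called 8 and 0.

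Leaving out 1 library at a time gave 28 to 1920, 1 to 47, 4 to 40, 0 to 24, 0 to 1196, 77 to 2708, 49 to 2090, 2 to 22 and 2 to 1031 genes, and 0 to 0 and 0 to 61 for the differences of responses. Leaving out either LPS-treated Socs1 knockout library raised most counts alike, since the spread within that pair then left the fit. The lists called ranged over 13 to 17, 5 to 15, 1 to 10, 6 to 13 and 3 to 15 in the first 5 comparisons, and over 0 to 8 and 2 to 11 for the differences of responses. Without the first LPS-treated Socs1 knockout library 14 and 0 calls were shared, and 822, 36, 33, 16 and 0 genes of the authors' tables were called.

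Of 3319 values of named genes under the alternatives, 2812 stayed on their side of the threshold, 460 no longer passed, 47 newly passed and 0 called values reversed. Among 1399 values called in neither setting 83 changed sign. With 2 libraries per group, simulated 2-fold changes of genes above a minimum mean count were rarely recovered (7% to 23%). Genes without a call may therefore have changed. For named genes that it removes the filter at a mean of 5 CPM, and for some genes with few counts the fit to the groups of a comparison, gave no value. The block for each genotype and replicate number gave named genes a value only for LPS in wild type and the differences of responses, and the crossed block gave a count alone.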

Other observations

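Some genes stood apart between the libraries of 1 genotype both without and after LPS. In the Socs1 knockout the MHC class II gene H2-Aa stood at 0.0433 CPM in the first and 10.7 CPM in the second untreated library, and at 0.0815 and 15.3 CPM after LPS. H2-Eb1, of the same class, stood at 0 and 7.51 CPM untreated and 0.0407 and 8.49 CPM after LPS. In the Ing4 knockout the complement gene C1qb stood at 0.436 and 9.72 CPM untreated and 0.38 and 9.41 CPM after LPS, the membrane protein gene Ms4a7 at 0.61 and 42.4 and at 1.95 and 62.5, and Cd207, known from Langerhans cells, at 1.18 and 59.5 and at 9.02 and 139. Ighm, the heavy chain of immunoglobulin M, went the other way, with 41.5 and 2.12 CPM untreated and 24.3 and 1.88 CPM after LPS. In wild type the serotonin receptor gene Htr1b stood at 43.9 and 6.47 CPM untreated and 17.8 and 1.72 CPM after LPS. Each pair gives the first and the second library, the genes were chosen after their values were seen, and with 1 library per value no test was made.

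Such genes, over 4-fold apart between the first and second library in the same direction without and after LPS, numbered 10 higher in the first and 14 higher in the second library in wild type, 6 and 49 in the Ing4 knockout and 62 and 166 in the Socs1 knockout. The number with opposite directions was 0, 0 and 2.

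Early transcription factor genes stood high in the first LPS-treated Socs1 knockout library. Egr3 stood at 234.5 CPM there and between 1.383 and 6.874 CPM in the other 5 LPS-treated libraries, and the nuclear receptor gene Nr4a1 at 157.9 against 1.719 to 2.737 CPM. Ifnb1, the interferon that drives the antiviral genes, stood at 5.906 CPM there against 9.07 to 27.2 CPM. These genes were chosen after their values were seen.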
